A study of Saccharomyces cerevisiae with 28 samples.

How the data were processed

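The series holds 28 Affymetrix yeast arrays of 8 groups, named after the labels: BY haploid, RM haploid, BY diploid and RM diploid (3 arrays each), hybrid diploid and mRNA mixture (6 each), and segregants and segregant hybrids (2 each). The deposited values are levels per probe set on a log2 scale, as judged from their range up to 14.67. The software the authors used to summarise and scale the arrays is not given in the sources used here, and no detection calls or bounds come with the values. Array medians lay within 7.34 and 7.56, so the values were used as deposited. Columns of per-sample values without a sample numbered 0. No pair of replicates in the 8 groups held identical values, and identical values made up at most 3.00% of probe sets in the closest pair.

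Of 9335 probe sets, 60 controls and 1 probe set at 0 on every array were left out, which left 9274. The platform annotation gave 6504 probe sets 1 gene, 328 several genes and 2442 none. All 6504 were matched to the R64 reference annotation through their gene identifiers, and no gene was named from a probe set with several. Probe sets whose identifiers end in f_at, s_at, i_at or r_at can share sequence with relatives, so the genes named from them (FDH1, MFA1 and HAP1 here) are uncertain. The arrays were designed on the reference sequence. A gene with several probe sets was named by the one with the highest mean, which left 5656 genes, and where other probe sets of a named gene gave another call this is given beside the value.

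Group means were fitted on 24 arrays of 6 groups with limma 3.58.1 in R 4.3.3 (lmFit and eBayes without trend), two-sided, with Benjamini-Hochberg adjustment over 9274 probe sets and a threshold of 0.05. The 4 segregant and segregant hybrid arrays stayed out of the fit because each may be another genotype. Strain differences are RM minus BY and ploidy differences diploid minus haploid. Hybrids and mixtures were compared with the log2 of the arithmetic mean of the parents' linear levels, with a delta-method standard error and limma's moderated variance. Strain by ploidy was a limma interaction. All differences are log2 values with SE.

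36 gene lists were fixed before the data were examined and tested with limma's camera, with a preset correlation of 0.01 and with an estimated one, on 1 probe set per gene, adjusted over the lists of a comparison. The results of 1 list are not reported here. With the preset correlation 15, 13, 13, 13, 10, 12, 5, 15 and 17 lists passed in the 9 comparisons in the order of the report, and 5, 4, 7, 7, 3, 5, 1, 4 and 3 passed with an estimated correlation. The pattern that defines cytoplasmic ribosomal proteins also takes RPP1, a subunit of RNase P. TAF1 in the iron list and SRP1 in the flocculin list now name other genes than the older symbols meant.

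The rule for named genes, fixed beforehand, took for the strain, ploidy, hybrid against midparent and hybrid against mixture comparisons the 8 largest rises and 8 largest falls among called single-gene probe sets with a standard name and no overlap between the groups' arrays (not demanded for the midparent), up to 4 called members of each list that passed, and a fixed set of mating and marker genes. For the other 3 comparisons it took 5 in each direction. The text names part of them.

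The fits and the list test were tested on simulated data. With 9274 probe sets and 100 changed by 1 on the log2 scale, 94% were recovered for the strain difference in haploids and 39% for the interaction, and with a change of 0.5 23% and 2%. For hybrid against midparent recovery was 97% and 60%. False calls were 4.88%, 6.82% and 3.68% of all calls in these. A simulated list shifted by 0.5 was found in the strain comparison, and 4% of 200 null lists had a p under 0.05. The simulated noise was independent between probe sets. It therefore does not show how often lists of genes that vary together pass by chance.

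Alternatives were quantile normalization, median centring, leaving out the dimmest 25% of probe sets, a floor at the 10th percentile (5.73), a fit on the compared groups alone or on all 28 arrays, a replicate block, array weights, a variance trend, 1 probe set per gene, the mean of log2 values as midparent, and leaving out each array in turn. Leaving out mixture replicate 5 from all comparisons, and hybrid replicates 1 and 6, were added after seeing the data, as were arithmetic midparents for the contrast beyond ploidy (values without a test) and hybrids against each parent for 2 lists. Positions between the parents used probe sets called for strain in haploids (mixtures and segregants) or diploids (hybrids), with Wilson intervals at 95%. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.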

Results

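Transcript levels were measured on 28 single-colour Affymetrix yeast arrays, each with 9335 probe sets, from Saccharomyces cerevisiae cells in log phase. BY is a laboratory strain with the genome of the reference strain S288C, and RM is a strain from a vineyard. Haploid and diploid cells of each strain gave 3 arrays per group. Diploid hybrids of BY and RM gave 6 arrays, and equal mixtures of BY and RM mRNA gave another 6. A further 2 arrays came from haploid segregants of the cross and 2 from diploids made by mating segregants. The series title names genotyping, expression and allele-specific expression as the aims. Only expression per probe set is compared here. Array medians lay between 7.34 and 7.56 on the log2 scale, and the number of arrays limits the precision. Within groups the correlation of arrays across probe sets was 0.956 or higher, except for mixture replicate 5, whose mean correlation with the other mixtures was 0.922. The labels do not say whether replicates were separate cultures, so p-values measure only the spread between these arrays, which may be technical.

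The first comparison asked how haploid RM differs from haploid BY. Mating genes differed between these haploids. The labels give neither mating types nor marker mutations. Differences in mating genes, HO, URA3, LEU2 and LYS2 therefore cannot be assigned to strain background, or to ploidy alone, here or in the comparisons below. All 7 measured a-specific genes, which cells of mating type a express, were higher in RM (7 adjusted over the list alone). MFA2, which encodes the a-factor pheromone, was higher by 5.67 ± 0.19 on the log2 scale (SE, n = 3 arrays per strain, limma adjusted p = 7.9e-17). STE2, the alpha-factor receptor, was higher by 4.86 ± 0.12 and BAR1, the protease that degrades alpha-factor, by 3.75 ± 0.11. All 4 alpha-specific genes were lower in RM (4 adjusted over the list alone), with a difference of -5.04 ± 0.16 for SAG1, the alpha-agglutinin, and -4.80 ± 0.18 for MF(ALPHA)1, an alpha-factor gene. GPA1, the G protein subunit that haploids of either mating type use, differed by -0.02 ± 0.12 (adjusted p = 0.94).

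Some biosynthetic genes also differed between the haploids. URA3, of pyrimidine synthesis, was lower in RM by -3.10 ± 0.17 (adjusted p = 9.6e-13) and LEU2, of leucine synthesis, by -2.82 ± 0.16 (adjusted p = 2.3e-12). LEU1, the enzyme before LEU2 in the pathway, was higher by 2.30 ± 0.14, the mitochondrial carrier OAC1 by 2.81 ± 0.15 and the transaminase BAT1 by 1.33 ± 0.11. Genes that share a pathway with URA3, LEU2 or LYS2 cannot be assigned to strain background either. OAC1 was at 8.99 in BY and 11.80 in RM haploids, but at 9.47 and 9.97 in diploids. Of 13 genes of branched-chain amino acid synthesis 7 were higher and 2 lower (7 and 2 adjusted over the list alone). The list test gave adjusted p = 0.042, and adjusted p = 0.306 with an estimated correlation. LYS2, of lysine synthesis, was higher in RM by 1.65 ± 0.26 (adjusted p = 2.9e-05). Of 7 arginine synthesis genes 4 were higher (4 adjusted over the list alone; adjusted p = 0.0485, and adjusted p = 0.598 with an estimated correlation). Leaving out 1 array ended the call of the leucine list for 2 arrays (highest adjusted p 0.0598, without RM haploid replicate 2) and of the arginine list for 5 (0.0809, without BY haploid replicate 3).

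Respiratory genes were higher in RM. Of 29 genes of the respiratory chain and cytochromes 26 were higher and 1 lower (27 and 1 adjusted over the list alone; list adjusted p = 3.1e-31). Cytochrome c, CYC1, was higher by 2.99 ± 0.12 and the succinate dehydrogenase subunit SDH2 by 2.13 ± 0.17. Of 17 ATP synthase genes 16 were higher (17 adjusted over the list alone; list adjusted p = 1.2e-17), INH1 by 1.77 ± 0.15. Ergosterol synthesis had 14 of 26 genes higher (16 higher and 2 lower adjusted over the list alone), ERG28 by 1.49 ± 0.12, and its adjusted p was 0.145 with an estimated correlation. General stress genes had 16 of 35 higher and 1 lower (23 and 1 adjusted over the list alone), with the catalase CTT1 higher by 3.10 ± 0.40, and their adjusted p was 0.598 with an estimated correlation. Mitochondrial ribosomal proteins had 23 of 67 higher (37 adjusted over the list alone; adjusted p = 0.442 with an estimated correlation).

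HO, the mating-type switching endonuclease, was lower in RM by -1.66 ± 0.17 (adjusted p = 4.8e-08). Of 27 iron regulon genes 4 were higher and 7 lower (4 and 8 adjusted over the list alone; adjusted p = 0.0863 with an estimated correlation), FET3 by -1.44 ± 0.22. Lists lower in RM with few called members were heat shock and chaperones (2 higher, 6 lower of 26; 2 and 7 adjusted over the list alone), purine synthesis (1 lower of 18; 0 adjusted over the list alone), ribosome biogenesis (1 lower of 56; 1 adjusted over the list alone) and cytoplasmic ribosomal proteins (3 lower of 81; 3 adjusted over the list alone). Their adjusted p-values with an estimated correlation were 0.598, 0.598, 0.772 and 0.815. The calls of the iron list (0.0542 without RM haploid replicate 3), of chaperones (0.0809) and of cytoplasmic ribosomal proteins (0.450, both without BY haploid replicate 3) ended without 1 array.

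In all, 1669 of 9274 probe sets differed between haploid strains, 917 higher and 752 lower in RM, and after median centring 738 and 860. Of the 599 that differed over 2-fold, 203 were higher and 396 lower. Single-gene probe sets called at any size gave 762 higher and 366 lower, and those over 2-fold 186 higher and 112 lower. One limit concerns probe sets of the same gene that disagreed: COX1, a mitochondrial cytochrome oxidase gene, was lower by -3.51 ± 0.19 by the probe set used for naming, whereas 2 other probe sets gave 0.61 and 0.53.

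The diploid strains were compared next. In diploids SAG1 was at 7.28 ± 0.08 in BY and 7.34 ± 0.30 in RM (SD, n = 3). STE3 differed by -0.09 ± 0.14 and MF(ALPHA)1 by 0.01 ± 0.18 (adjusted p = 0.74 and 0.98). Of 7 a-specific genes 1 was higher and 1 lower in RM (3 and 1 adjusted over the list alone; list adjusted p = 0.470). Arginine synthesis genes were higher in RM, with all 7 called (7 adjusted over the list alone). ARG1 was higher by 3.06 ± 0.30 (adjusted p = 4.9e-08) and CPA1 by 2.22 ± 0.26. The list gave adjusted p = 0.0713 with an estimated correlation. Lysine synthesis had 5 of 9 higher (5 adjusted over the list alone; adjusted p = 0.365 with an estimated correlation), and sulfur amino acid synthesis had 10 higher and 2 lower of 23 (11 and 2 adjusted over the list alone; list adjusted p = 0.000182, and 0.0461 with an estimated correlation). Leucine and branched-chain synthesis had 2 higher and 1 lower of 13 and did not pass (2 and 1 adjusted over the list alone; list adjusted p = 0.738).

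Phosphate genes were lower in RM diploids. Of 18 targets of the transcription factor Pho4, 10 were lower and 1 higher (10 and 1 adjusted over the list alone; list adjusted p = 1.9e-07). The phosphate transporter PHO84 differed by -5.03 ± 0.15 (adjusted p = 2.2e-17), SPL2 by -3.19 ± 0.22 and the acid phosphatase PHO5 by -2.82 ± 0.11. Respiratory chain genes were again higher in RM, 25 of 29 with 1 lower (27 and 1 adjusted over the list alone), with CYC1 at 2.69 ± 0.12. ATP synthase had 14 of 17 higher (14 adjusted over the list alone; adjusted p = 0.159 with an estimated correlation), mitochondrial ribosomal proteins 29 of 67 (40 adjusted over the list alone; adjusted p = 0.159 with an estimated correlation) and ergosterol synthesis 13 higher and 2 lower of 26 (13 and 3 adjusted over the list alone; adjusted p = 0.159 with an estimated correlation). General stress genes were higher in 9 of 35 (14 higher and 1 lower adjusted over the list alone; adjusted p = 0.608 with an estimated correlation).

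URA3 and LEU2 differed by -0.27 ± 0.17 and -0.30 ± 0.16 in diploids and did not pass the test (adjusted p = 0.34 and 0.25), though LEU2 passed in a fit on these groups alone. Ribosome biogenesis had 5 of 56 lower (1 adjusted over the list alone), heat shock and chaperones 6 lower and 1 higher of 26 (11 and 1 adjusted over the list alone) and G1 cyclins and G1/S genes 3 of 17 lower (3 adjusted over the list alone). With an estimated correlation their adjusted p-values were 0.652, 0.534 and 0.534. The G1 call ended without any of 3 arrays (highest adjusted p 0.0815, without BY diploid replicate 3). Counts came to 1598 probe sets, 686 higher and 912 lower in RM, of which 537 differed over 2-fold. This balance turned after quantile normalization (973 higher, 925 lower), after median centring (872 and 804) and in single-gene probe sets (582 and 561). Of the probe sets called in both haploids and diploids 962 had the same direction and 13 the opposite one. Independent lists would share 67.8 higher and 74.0 lower, against 398 and 564 observed. A fit on these groups alone called 2478.

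Strain differences that depended on ploidy were tested as an interaction, the RM minus BY difference in diploids minus that in haploids. Among the named genes PHO84 moved most, by -5.46 ± 0.21 (adjusted p = 1.1e-14). The difference moved by 5.11 ± 0.22 for SAG1 and by -5.20 ± 0.26 for MFA2, and all 7 a-specific and 4 alpha-specific genes were called (7 and 4 adjusted over the list alone). Of 18 phosphate genes 7 moved down (9 adjusted over the list alone; list adjusted p = 6.5e-17). URA3 moved by 2.83 ± 0.24, LEU2 by 2.53 ± 0.23, ARG3 by 2.93 ± 0.43 and HO by 1.86 ± 0.24, while LYS2 at -0.21 ± 0.36 did not pass (adjusted p = 0.95). Arginine synthesis genes moved up in 3 of 7 cases (5 adjusted over the list alone; list adjusted p = 2.6e-11). Pheromone response had 3 up and 1 down of 25 (6 and 1 adjusted over the list alone; list adjusted p = 1.9e-06), and galactose and maltose use passed with 0 of 13 members called (0 adjusted over the list alone; list adjusted p = 0.0114, and 0.0717 without BY haploid replicate 3).

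Respiratory chain genes moved down in 3 of 29 cases (9 adjusted over the list alone) and ATP synthase in 0 of 17 (6 adjusted over the list alone), with adjusted p = 0.292 and 0.196 with an estimated correlation. Leucine synthesis had 1 up and 3 down of 13 (1 and 4 adjusted over the list alone), lysine synthesis 0 of 9 (2 adjusted over the list alone), sulfur amino acid synthesis 1 up of 23 (4 adjusted over the list alone) and mitochondrial ribosomal proteins 0 of 67 (0 adjusted over the list alone). Their adjusted p-values were 0.131, 0.292, 0.131 and 0.614 with an estimated correlation. The mitochondrial ribosome call ended without either of 2 arrays (0.136 without RM haploid replicate 2). The test called 181 probe sets, 106 with a higher and 75 with a lower difference in diploids, so that 58.6% were higher. That share was 71.8% after median centring and 39.3% with 1 probe set per gene, and single-gene probe sets gave 55 higher and 69 lower. Without mixture replicate 5 in the fit, a choice made after seeing the data, the count was 296.

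**Figure D1:**
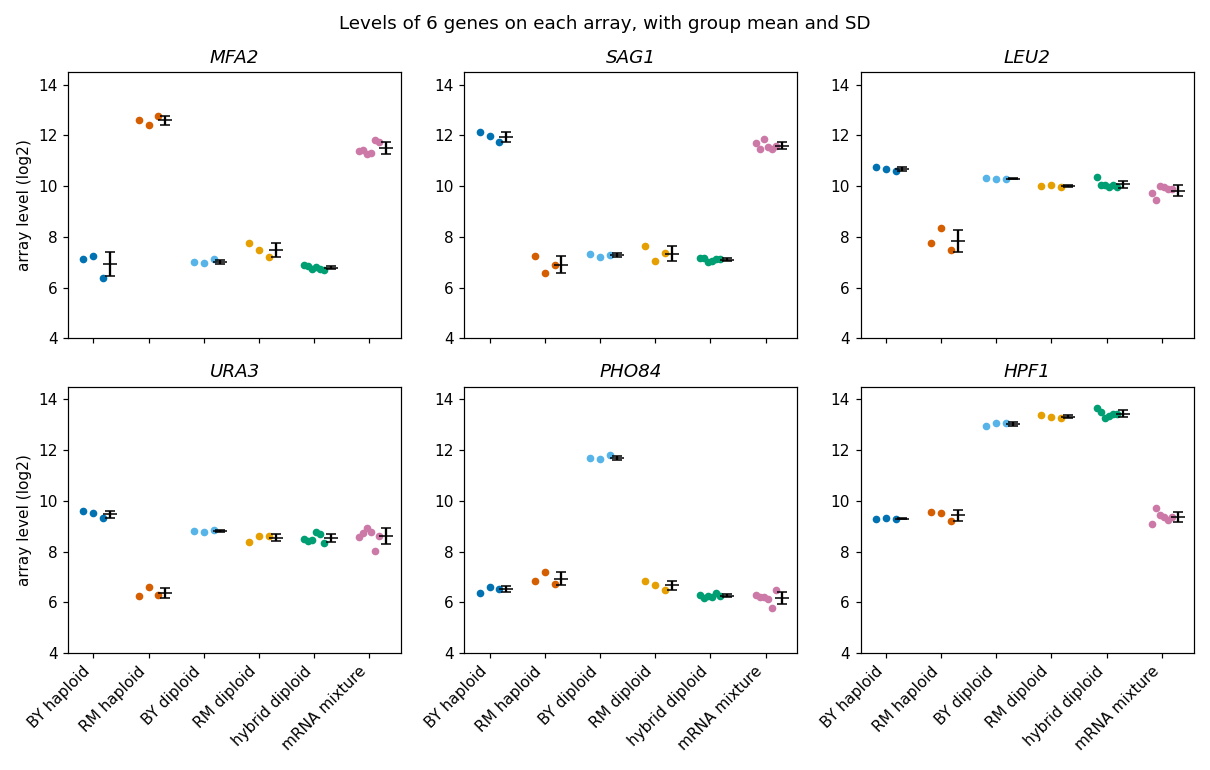
Log2 level of 6 genes (vertical axes) on every array of 6 groups (horizontal axis); points are arrays and the black bar and whiskers are the group mean and SD. MFA2 is high in RM haploids and SAG1 in BY haploids, each also in the mixtures; PHO84 is high in BY diploids alone among these groups, and HPF1 in the 3 kinds of diploid.

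Ploidy was compared within BY first. Haploid and diploid groups of a strain may also differ in mating type or markers, which the labels do not give. The ploidy differences, and the contrast beyond ploidy below, therefore cannot be assigned to ploidy alone. Alpha-specific and haploid genes fell in BY diploids: all 4 alpha-specific genes fell (4 adjusted over the list alone), SAG1 by -4.67 ± 0.16 and MF(ALPHA)1 by -5.17 ± 0.18 (adjusted p = 1.0e-15). Of 12 genes repressed in a/alpha cells 11 fell (12 adjusted over the list alone; list adjusted p = 4.9e-64), among them the cyclin-dependent kinase inhibitor FAR1 by -4.07 ± 0.15, GPA1 by -2.12 ± 0.12, RME1 by -2.16 ± 0.24 and HO by -2.04 ± 0.17. Of 25 pheromone response genes 9 fell (10 adjusted over the list alone; list adjusted p = 8.6e-23), AGA1 by -2.51 ± 0.14. AFB1 fell by -4.65 ± 0.16.

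Phosphate genes rose in BY diploids, 9 of 18 (12 adjusted over the list alone; list adjusted p = 1.4e-20). PHO84 rose by 5.19 ± 0.15, SPL2 by 3.22 ± 0.22, PHO5 by 2.91 ± 0.11 and the vacuolar transporter chaperone gene VTC3 by 1.80 ± 0.14. The cell wall gene HPF1 rose by 3.72 ± 0.13 (adjusted p = 1.1e-15). Zinc regulon genes had 5 rising and 1 falling of 11 (6 and 1 adjusted over the list alone; list adjusted p = 2.4e-05), the zinc transporter ZRT3 by 0.96 ± 0.15 and the transcription factor ZAP1 by 0.88 ± 0.17. Respiratory chain genes rose in 20 of 29 cases (25 adjusted over the list alone; list adjusted p = 1.4e-20), QCR6 by 0.82 ± 0.13, and ATP synthase genes in 8 of 17 (14 adjusted over the list alone; adjusted p = 0.0674 with an estimated correlation). LYS2 rose by 1.26 ± 0.26, and FIT2, a cell wall mannoprotein of iron uptake, fell by -1.61 ± 0.33. The iron list had 1 rising and 2 falling of 27 (1 and 2 adjusted over the list alone; list adjusted p = 0.000376).

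Other lists passed with few members called: mitochondrial ribosomal proteins (2 of 67 up, 1 adjusted over the list alone), the subtelomeric COS family (1 of 8 up, 4 adjusted over the list alone; the list also asked for YRF1 genes, but none was measured), seripauperins (0 of 10, 0 adjusted over the list alone) and thiamine synthesis (0 of 11, 0 adjusted over the list alone). With an estimated correlation their adjusted p-values were 0.549, 0.228, 0.312 and 0.0637. Calls that ended without 1 array were those of seripauperins (0.0669 without BY diploid replicate 3) and thiamine synthesis (0.0620 without BY haploid replicate 3). Ribosome biogenesis passed as lower although its median was 0.06, with 0 of 56 called (0 adjusted over the list alone; adjusted p = 0.979 with an estimated correlation), and 0.0649 without BY haploid replicate 1. In BY, 589 probe sets changed, 216 up and 373 down. The share going up was 36.7%, and 23.6% after median centring, which moved the median of all probe sets from 0.11 to 0.01. Single-gene probe sets went mostly the other way, 189 up and 92 down, as did array weights (60.2% up) and 1 probe set per gene (66.7% up).

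In RM, a-specific and haploid genes were lower in diploids than in haploids. Of 7 a-specific genes 6 fell (7 adjusted over the list alone; list adjusted p = 3.2e-34), MFA2 by -5.10 ± 0.19, STE2 by -4.40 ± 0.12 and the protease gene BAR1 by -3.96 ± 0.11. Of 12 haploid-specific genes 9 fell (11 adjusted over the list alone; list adjusted p = 1.7e-26), FAR1 by -3.45 ± 0.15, RME1 by -2.57 ± 0.24 and GPA1 by -1.98 ± 0.12. HPF1 rose in RM diploids too, by 3.89 ± 0.13 (adjusted p = 8.2e-16). URA3 was higher in RM diploids by 2.17 ± 0.17 and LEU2 by 2.14 ± 0.16. In BY their values were -0.66 ± 0.17 and -0.38 ± 0.16, and the interaction above tests that difference. LEU2 was at 7.49 to 8.33 in RM haploids, 9.96 to 10.03 in RM diploids and 10.28 to 10.32 in BY diploids. URA3 was at 6.24 to 6.61, 8.39 to 8.63 and 8.78 to 8.85. A marker difference between RM haploids and RM diploids cannot be told apart from ploidy here.

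Arginine synthesis rose in 7 of 7 genes in RM diploids (7 adjusted over the list alone; adjusted p = 0.0627 with an estimated correlation), ARG3 by 3.24 ± 0.30 and CPA1 by 2.34 ± 0.26. Lysine synthesis rose in 4 of 9 (6 adjusted over the list alone; adjusted p = 0.16 with an estimated correlation), LYS20 by 1.49 ± 0.23. Mitochondrial ribosomal proteins rose in 11 of 67 (22 adjusted over the list alone; adjusted p = 0.345 with an estimated correlation) and the zinc regulon in 2 of 11 (2 adjusted over the list alone; adjusted p = 0.116 with an estimated correlation), IZH2 by 0.65 ± 0.12.

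Of pheromone response genes 4 fell and 1 rose among 25 in RM (8 and 1 adjusted over the list alone; adjusted p = 0.316 with an estimated correlation), TEC1 by -2.38 ± 0.22. The mitotic CLB2 cluster had 2 of 15 falling (2 adjusted over the list alone; adjusted p = 0.471 with an estimated correlation), SWI5 by -0.73 ± 0.11, and ribosome biogenesis 0 of 56 (0 adjusted over the list alone; adjusted p = 0.91 with an estimated correlation). These calls ended without RM diploid replicate 3 for pheromone response (0.0798), RM haploid replicate 1 for the mitotic cluster (0.0819) and RM diploid replicate 1 for ribosome biogenesis (0.230). RM gave 764 changed probe sets, 344 up and 420 down, although single-gene probe sets gave 296 up and 189 down and 1 probe set per gene 310 and 162. The count was 1172 without mixture replicate 5 in the fit, chosen after seeing the data. Of those called in either strain 326 were called in both, 322 of them with the same direction, where independent lists would share 8.01 higher and 16.9 lower against 39 and 283 observed.

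Diploid hybrids were then set against the arithmetic mean of BY and RM diploids. Respiratory genes were higher in the hybrids: 26 of 29 genes of the respiratory chain (28 adjusted over the list alone; list adjusted p = 4.9e-33) and 17 of 17 ATP synthase genes (17 adjusted over the list alone; list adjusted p = 1.7e-19). The lactate dehydrogenase CYB2 was higher by 1.62 ± 0.22, CYC1 by 1.02 ± 0.09 and ATP7 by 1.02 ± 0.10 (SE, n = 6 hybrids and 3 of each parent, limma adjusted p = 5.4e-05, 2.7e-07 and 7.8e-07). Mitochondrial ribosomal proteins were higher in 40 of 67 cases (50 adjusted over the list alone; list adjusted p = 7.4e-20). The mitochondrial gene COB had the largest rise, 2.75 ± 0.24, by the probe set used for naming, while its other probe set gave 0.59. By the former it had means of 8.60 in hybrids, 4.47 in BY and 6.54 in RM diploids. Segregant hybrids had 8.24, and haploid segregants 7.745 against 4.34 in BY and 6.45 in RM haploids. A level above both parents was therefore not particular to the hybrids. On each of the 6 hybrid arrays the mean of the respiratory list lay above all parental diploid arrays, from 10.8 to 11.2 against 9.63 to 10.7.

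Ribosome biogenesis genes were lower in the hybrids, 50 of 56 (53 adjusted over the list alone), with NSR1 at -1.12 ± 0.25 and NOP7 at -1.03 ± 0.21. General stress genes were higher in 26 of 35 cases (32 adjusted over the list alone), the small heat shock protein HSP26 by 1.48 ± 0.32, with hybrid replicate 1 at 10.17 and the others at 7.53 to 8.20, and CTT1 by 1.44 ± 0.31. The adjusted p-values were 0.27 and 0.228 with an estimated correlation. The hybrid arrays differed among themselves in these groups: the ribosome biogenesis mean ranged from 7.44 to 8.87 against 8.52 to 9.20 in the parental diploids, and the stress mean from 9.44 to 11.08 against 8.79 to 9.52. Without hybrid replicates 1 and 6, chosen after seeing the data, 24 ribosome biogenesis genes were lower and 13 stress genes higher, with medians of -0.474 and 0.555 against -0.787 and 0.859 with all 6.

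Phosphate genes lay below the midparent, 9 of 18 (10 lower and 1 higher adjusted over the list alone; list adjusted p = 7.4e-20), PHO84 by -4.49 ± 0.12 and PHO5 by -2.13 ± 0.09. PHO84 was at 6.26 ± 0.06 in the hybrids (SD, n = 6), 11.7 ± 0.08 in BY diploids and 6.67 ± 0.18 in RM diploids (SD, n = 3). The glucose transporter HXT1 was lower by -1.74 ± 0.29, the membrane protein gene INA1 by -2.03 ± 0.22 and the ammonium exporter gene ATO3 by -1.42 ± 0.20. Arginine synthesis was higher in 5 of 7 (6 adjusted over the list alone; adjusted p = 0.25 with an estimated correlation). FDH1, formate dehydrogenase, was higher by 1.85 ± 0.19 by a probe set that can share sequence with relatives. A probe set of FDH1 without that mark gave 0.75, and another one with it 1.79.

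Heat shock and chaperone genes were higher in 9 of 26 (11 higher and 2 lower adjusted over the list alone). Sulfur amino acid synthesis was lower in 8 of 23 (8 lower and 1 higher adjusted over the list alone), MET2 by -0.69 ± 0.10. The zinc regulon had 5 lower and 1 higher of 11 (5 and 1 adjusted over the list alone), and cytoplasmic ribosomal proteins 5 of 81 lower (0 adjusted over the list alone). With an estimated correlation the adjusted p-values were 0.27, 0.151, 0.0745 and 0.884. The sulfur call ended without hybrid replicate 4 (0.138) and that of ribosomal proteins without hybrid replicate 1 (0.668). The comparison called 1675 probe sets, 604 higher and 1071 lower, or 36.1% higher. Median centring gave 50.4%. The count was 2657 without mixture replicate 5 and 685 without hybrid replicates 1 and 6.

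**Figure D2:**
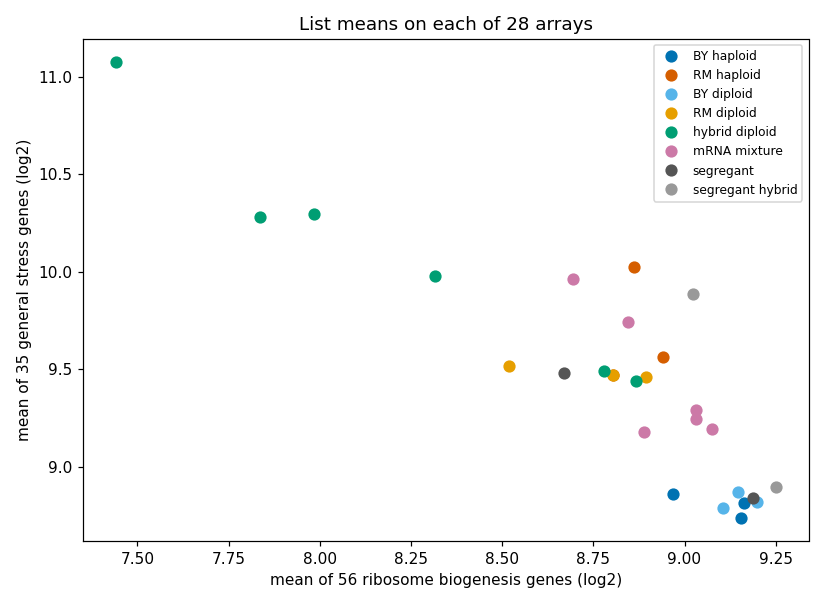
Mean log2 level of 56 ribosome biogenesis genes (horizontal axis) against that of 35 general stress genes (vertical axis) on each of 28 arrays, coloured by group. The 6 hybrid arrays spread along a line from 8.87 and 9.44 to 7.44 and 11.08, and 4 of them lie outside the range of all parental diploid arrays on both axes.

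The mRNA mixtures, described as equal, were set against the arithmetic mean of the haploid parents, as a measure of how the arrays report a mixture. Unequal amounts of BY and RM mRNA are left open below, and would also move the departures given here. Departures were small, with 2 of 791 called probe sets over 2-fold. SAG1 lay above the midparent by 0.61 ± 0.13 (adjusted p = 0.0083), and alpha-specific genes as a list were above it with 1 of 4 called (3 adjusted over the list alone; list adjusted p = 0.000283, and adjusted p = 0.0314 with an estimated correlation). The small nucleolar RNA gene SNR67 lay below by -0.93 ± 0.16, RGI2 by -0.91 ± 0.16 and the meiotic gene MND1 by -0.70 ± 0.12. The succinate dehydrogenase subunit gene SDH3 lay above by 0.57 ± 0.10. RGI2 and MND1 had mixture levels near the floor of 5.73 that served as an alternative. RGI2 was at 5.45 in mixtures, 5.93 in BY and 6.69 in RM haploids, and MND1 at 5.945, 6.46 and 6.8. Weak signals could not be told from none, so background is left open for both genes. On mixture replicate 5, which stood apart, VPS8 and MND1 departed from the other mixtures.

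Early meiosis genes were below the midparent in 5 of 18 (5 adjusted over the list alone) and seripauperins in 4 of 10 (6 adjusted over the list alone), while respiratory genes were above it in 2 of 29 (1 adjusted over the list alone). Their adjusted p-values were 0.197, 0.197 and 0.834 with an estimated correlation. The respiratory call ended without mixture replicate 2 (0.0552). There were 142 probe sets above and 649 below the midparent. After leaving out the dimmest 25% of probe sets, 112 lay above and 215 below. A fit on the 3 compared groups called 1, and 292 were called without RM haploid replicate 2, 472 without BY haploid replicate 2 and 513 without mixture replicate 1.

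Hybrids against mixtures compared BY and RM genomes joined within a diploid cell with mixed RNA of BY and RM haploids. Whether mating-type and marker alleles were the same in both is not in the labels. Mating genes were lower in the hybrids: 6 of 7 a-specific genes, with MFA2 at -4.70 ± 0.13 and STE2 at -3.91 ± 0.09 (6 adjusted over the list alone; list adjusted p = 2.5e-17), and 4 of 4 alpha-specific genes, with SAG1 at -4.49 ± 0.11 (SE, n = 6 arrays per group; 4 adjusted over the list alone; list adjusted p = 2.0e-15). All 12 haploid-specific genes were lower (12 adjusted over the list alone; list adjusted p = 1.9e-23), FAR1 by -4.10 ± 0.11 and GPA1 by -2.23 ± 0.08. Pheromone response genes had 9 lower and 1 higher of 25 (9 and 1 adjusted over the list alone; list adjusted p = 9.3e-07). HPF1 was higher by 4.07 ± 0.09 and the zinc-regulated gene ZPS1 by 3.02 ± 0.37.

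Mitochondrial ribosomal proteins were higher in 61 of 67 cases (64 adjusted over the list alone), the respiratory chain in 27 of 29 (27 adjusted over the list alone), ATP synthase in 17 of 17 (17 adjusted over the list alone) and arginine synthesis in 7 of 7 (7 adjusted over the list alone). Their adjusted p-values were 0.054, 0.054, 0.0711 and 0.0854 with an estimated correlation. ARG3 was higher by 3.36 ± 0.21, CYC1 by 1.14 ± 0.08 and MRPL40 by 0.84 ± 0.14. Ribosome biogenesis genes were lower in 50 of 56 (52 adjusted over the list alone; adjusted p = 0.258 with an estimated correlation), RLP24 by -1.14 ± 0.22, and general stress genes higher in 23 and lower in 1 of 35 (24 and 1 adjusted over the list alone; adjusted p = 0.693 with an estimated correlation), the glycogen branching enzyme GLC3 by 1.45 ± 0.24. These are the groups in which the hybrid arrays differed among themselves.

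Pyrimidine synthesis had 6 lower and 2 higher of 13 (6 and 2 adjusted over the list alone), with URA1 at -2.02 ± 0.23 and CPA1 at 2.10 ± 0.19. URA1 shares the pathway of URA3 and carries the marker limit given above. It was at 9.91 in BY and 12.20 in RM haploids, and at 10.29 and 10.27 in diploids. Lysine synthesis was higher in 7 of 9 (7 adjusted over the list alone) and the COS family in 5 of 8 (6 adjusted over the list alone), and cytoplasmic ribosomal proteins had 1 lower of 81 (0 adjusted over the list alone). With an estimated correlation the adjusted p-values were 0.109, 0.246, 0.405 and 0.767. Calls ended without mixture replicate 5 for the COS family (0.0833) and without hybrid replicate 1 for ribosomal proteins (0.662). Of all probe sets 2611 differed, 1588 higher and 1023 lower in hybrids. Of these 484 were also called for ploidy in BY, 476 with the same direction, and 577 for ploidy in RM, 560 with the same direction, from separate arrays. Independent lists would share 37.0 higher and 41.1 lower with BY, against 112 and 364 observed, and 58.9 higher and 46.3 lower with RM, against 204 and 356.

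The last of these contrasts subtracted the parents' ploidy difference, as means of log2 values, from hybrid against mixture. COB, by the same probe set as above, was higher by 2.74 ± 0.32, FDH1 by 2.09 ± 0.23, ARG3 by 1.58 ± 0.30 and the cytochrome oxidase subunit COX26 by 1.70 ± 0.23. COB also lay above both parents in segregants and segregant hybrids, as given above. For FDH1 the probe set not marked as able to share sequence gave 1.10, and the remaining one 2.21. PHO84 was lower by -2.39 ± 0.15, SAG1 by -2.38 ± 0.16 and MFA2 by -2.20 ± 0.19. The PHO84 value comes from the BY diploids, at 11.63 to 11.79, and not from a fall in hybrids against mixtures. Hybrid arrays had PHO84 at 6.18 to 6.35 and mixtures at 5.76 to 6.50. For genes expressed mostly in 1 parent the arithmetic mean lies above the mean of log2 values, by 1.56 for SAG1 and 1.86 for MFA2 in haploids, which lowers their values here, and by 1.56 for PHO84 and 1.45 for ARG3 in diploids, which raises theirs. With arithmetic midparents, a choice made after seeing the data, the values were -0.81 for SAG1, -0.36 for MFA2, -3.93 for PHO84, 0.42 for ARG3, 2.76 for COB, 1.88 for FDH1 and 1.62 for COX26. The a-specific list had 5 of 7 lower (5 adjusted over the list alone) and the alpha-specific list 4 of 4 (4 adjusted over the list alone), but their medians moved from -0.94 to 0.01 and from -2.06 to -0.67 with arithmetic midparents, so the a-specific call rests on the offset.

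Respiratory genes were higher beyond ploidy in 16 of 29 (23 adjusted over the list alone), ATP synthase in 9 of 17 (13 adjusted over the list alone), mitochondrial ribosomal proteins in 11 of 67 (24 adjusted over the list alone), arginine synthesis in 3 of 7 (6 adjusted over the list alone; median 0.995, and 0.63 with arithmetic midparents) and general stress in 4 of 35 (13 adjusted over the list alone). Their adjusted p-values were 0.0976, 0.0976, 0.128, 0.197 and 0.317 with an estimated correlation. Ribosome biogenesis was lower in 7 of 56 (32 adjusted over the list alone; adjusted p = 0.287 with an estimated correlation). The phosphate list, which had passed as higher in BY diploids than in BY haploids, had 5 of 18 lower (7 adjusted over the list alone). Sulfur amino acid synthesis had 6 of 23 lower (8 lower and 1 higher adjusted over the list alone). The zinc regulon had 4 lower and 1 higher of 11 (5 and 1 adjusted over the list alone) and pyrimidine synthesis 2 of 13 lower (4 lower and 1 higher adjusted over the list alone). With an estimated correlation these gave adjusted p = 0.0976, 0.248, 0.0976 and 0.248. The sulfur call ended without any of 11 arrays (highest adjusted p 0.173, without hybrid replicate 4) and the pyrimidine call without mixture replicate 5 (0.0598).

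Haploid-specific genes (0 of 12, 0 adjusted over the list alone), cytoplasmic ribosomal proteins (0 of 81, 0 adjusted over the list alone), seripauperins (0 of 10, 0 adjusted over the list alone) and chaperones (1 of 26 higher, 2 adjusted over the list alone) passed with few calls, and their adjusted p-values were 0.248, 0.639, 0.525 and 0.525 with an estimated correlation. Each of these 4 calls ended without 1 array, with adjusted p up to 0.119 (hybrid replicate 4), 0.0574 (hybrid replicate 1), 0.141 (RM haploid replicate 2) and 0.103 (hybrid replicate 1). In total 477 probe sets were called, 188 higher and 289 lower. The share higher was 39.4%, 49.7% after quantile normalization and 60% after median centring. The count was 777 without hybrid replicate 4, 310 without mixture replicate 3 and 292 without hybrid replicates 1 and 6. The lists of glycolysis, gluconeogenesis, hexose transport, loci of variable copy number, flocculins, histones and silencing passed in 0 of the 9 comparisons.

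Each array was also placed between the parents, as the share of strain-called probe sets nearer the RM mean. Mixtures gave 34.2% ± 7.74 and hybrids 54.5% ± 7.65 (SD, n = 6). Over probe sets that differed between strains by over 1 in log2, mixtures gave 29.8% ± 6.96 and hybrids 40.6% ± 7.36, with 5 of 6 hybrids under 50%. A share of 50% does not mark the middle, because on the log2 scale an equal mixture lies nearer the parent with the higher level. Probe sets higher in RM were 54.9% of the 1669 in haploids and 42.9% of the 1598 in diploids. Among those over 1 in log2 they were 203 of 599 and 186 of 537. Segregant 1 gave 36.2% and segregant 2 25.2%, with 95% Wilson intervals from 34.0 to 38.6 and from 23.2 to 27.4 over 1669 probe sets. The segregant hybrids gave 40.2% and 34.7% over 1598 probe sets. Probe sets are not independent, so the intervals are too narrow.

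Mating genes were also read on the segregant arrays, each reported alone. Both segregants had STE3, the a-factor receptor, at 10.91 and 10.93 and STE2 at 6.03 and 6.18, near the BY haploid means of 10.68 and 6.06. In the segregant hybrids MF(ALPHA)1 was at 7.84 and 7.94 and STE2 at 6.01 and 6.49. LEU2 was at 7.43 in segregant 1 and 10.47 in segregant 2, where RM haploids had 7.85 ± 0.43 and BY haploids 10.68 ± 0.08 (SD, n = 3). LYS2 was at 7.02 and 7.23 in the segregants, against 7.54 ± 0.08 in BY and 9.19 ± 0.26 in RM haploids, and HO at 6.62 and 6.59, against 8.74 ± 0.18 and 7.08 ± 0.28.

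**Figure D3:**
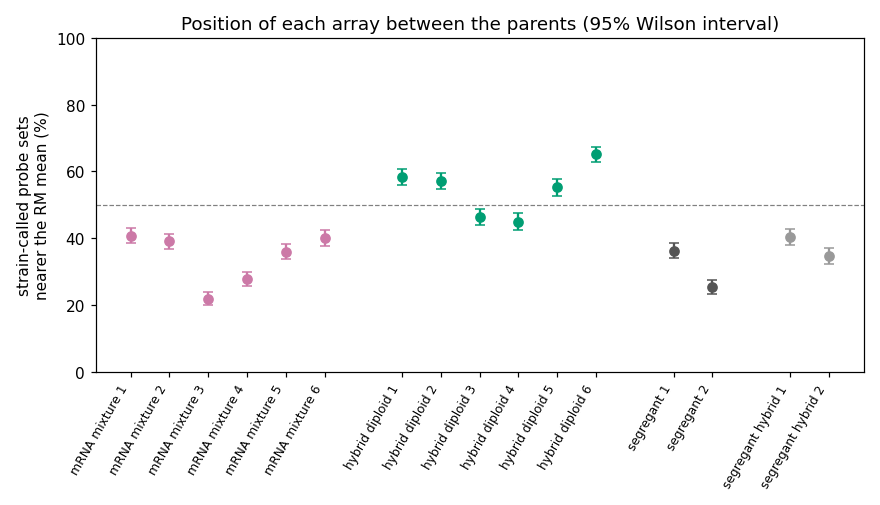
Percent of strain-called probe sets nearer the RM than the BY mean (vertical axis) on each mixture, hybrid, segregant and segregant hybrid array (horizontal axis). Whiskers are 95% Wilson intervals and the dashed line marks 50%. The line is not the value of an equal mixture, which on the log2 scale lies nearer the parent with the higher level. All 6 mixtures lie between 21.7% and 40.7%, and the hybrids between 44.9% and 65.1%.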

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

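Of the tests given here, those of unequal mRNA amounts, compression, a few hybrid arrays, scaling, hybrids against each parent, repeated or unnamed sequences, and the splits into which no group difference enters were chosen after their results were seen.

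Differences between strains were unlike in haploids and diploids for mating, phosphate and arginine synthesis genes, among others, by a test of the interaction that called 181 probe sets. On the log2 scale the RM minus BY difference in diploids minus that in haploids was -5.46 for PHO84, 5.11 for SAG1, 5.07 for MF(ALPHA)2, 4.81 for MF(ALPHA)1, 2.81 for STE3 and 3.08 for AFB1. For a-specific genes it was -5.20 for MFA2, -4.42 for STE2, -4.10 for BAR1, -3.26 for AGA2 and -2.33 for MFA1. ARG3 gave 2.93, URA3 2.83, LEU2 2.53 and HO 1.86. The MFA1 value comes from a probe set that can share sequence with relatives. The labels give neither mating types nor marker mutations, so the values of mating genes, HO, URA3 and LEU2 cannot be assigned to strain background or to ploidy alone. For phosphate and arginine genes too, other genotype differences between the haploid and diploid groups cannot be told apart from ploidy.

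Mixture replicate 5 stood far from the other mixtures. Its mean correlation with them was 0.922 and its 10th percentile 5.28. VPS8 was at 8.83 there against 7.24 to 7.54 on the other 5 mixtures, MND1 at 5.48 against 5.95 to 6.16 and the small nuclear RNA gene SNR14 at 5.60 against 6.11 to 6.37. The heat shock gene HSP26 was at 10.17 on hybrid replicate 1 against 7.53 to 8.20 on the other hybrids. In all 77 sets of values were tested this way and 6 gave such an array, where chance gives about 1 in 20, or 3.85; 5 of the 6 were mixture replicate 5.

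Ribosome biogenesis genes were lower and general stress genes higher in the hybrids than at the midparent of the diploids. Against BY diploids alone 51 of 56 were lower and 29 of 35 higher (53 and 33 adjusted over each list alone), and against RM diploids alone 11 and 9 (30 and 11 adjusted over each list alone), with medians of -0.56 and 0.55. The list calls against the midparent were lost with an estimated correlation (adjusted p = 0.27 and 0.228), and without hybrid replicates 1 and 6 the called members fell from 50 to 24 and from 26 to 13, while the medians kept their direction, from -0.787 to -0.474 and from 0.859 to 0.555. Scaling of the arrays is argued against: after median centring the ribosome biogenesis median was -0.73, against -0.79 as deposited, with 48 of 56 members lower. The growth state of the cultures at harvest may contribute: over the 6 hybrid arrays the means of both lists had Pearson r = -0.979 (exact permutation p = 0.00278) and Spearman rho = -0.943 (exact permutation p = 0.0167), with r = -0.983 without the 2 farthest arrays; 1 relation was computed. That relation lies between hybrid arrays, which may not be separate cultures. It therefore cannot separate growth from other sources of the difference from the parents. A few hybrid arrays as the source cannot be told apart from the group, since 4 of 6 lay outside all parental arrays in both lists. The hybrid genotype stays open as well, untested apart from growth.

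Mixtures lay nearer BY than RM over the strain-called probe sets, with 34.2% nearer RM where 54.9% were higher in RM. Among those over 1 in log2 the share was 29.8%, where 203 of 599 were higher in RM. Equal compression of strong signals in both mating-type lists is argued against as the only source, since together they gave an RM share of 0.371 ± 0.0312 (SD, n = 6) where it leaves 0.5. Stronger compression of 1 list could also move this mean. Unequal amounts of BY and RM mRNA may have a part, but cannot be told apart from other sources: the share averaged over probe sets higher and lower in RM was 0.405, with 0.474 ± 0.118 in the former, within its SD of 0.5, and 0.336 ± 0.139 in the latter. The a-specific list gave 0.434 ± 0.041 and the alpha-specific list 0.309 ± 0.0362. Compression alone would put the a-specific share, of genes higher in RM, above 0.5, where only mixture replicate 6 lay, at 0.509. No biological explanation was tested.

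Strain differences over 2-fold in haploids were mostly lower in RM, 396 against 203. Repeated and unnamed sequences such as transposons may explain this excess: among single-gene probe sets 37.6% were lower (112 of 298, exact 95% interval 32.1 to 43.4), while probe sets with several genes gave 91 lower and 3 higher and unnamed ones 193 and 14. Probe mismatches to the RM sequence cannot be told apart from the strain difference for these genes. The disagreement between probe sets of a gene was 1.38 times that for ploidy in BY (197 of 315 genes larger, sign test p = 1.0e-05), but 17 of 21 genes lower in RM and 6 of 9 higher held such a probe set (Fisher's exact p = 0.640). Its median was 0.327 for strain and 0.31 for ploidy in RM. The genotype stays open as an untested biological source.

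Other splits of the same arrays gave these counts. In comparisons of 3 against 3 arrays the 10 splits are too few for a share under 0.05: strain in haploids gave 1669 against a highest other of 24, strain in diploids 1598 against 0, ploidy in BY 589 against 0 and ploidy in RM 764 against 59, with 1 split as large in each, the real one. For hybrid against mixture 1 of 100 splits, the real one, gave as many (2611 against a highest other of 1617), a share under 0.05. Here too the other splits had a higher median residual SD, at least 0.240 against 0.226. This argues against a chance assignment of these arrays alone. Whether arrays were separate cultures is not known, so chance differences between cultures stay open. The splits do not decide for hybrid against midparent (1 of 100, 1675 against 700), mixture against midparent (2 of 100, 791 against 806) and hybrid against mixture beyond ploidy (1 of 100, 477 against 352): they put BY and RM arrays, or haploids and diploids, into 1 group, which adds the parents' differences to the spread whatever hybrids and mixtures do. The median residual SD was 0.226 in the real grouping and at least 0.240, 0.235 and 0.270 in the other splits of these 3. For the strain by ploidy interaction 15 of 100 splits, the real one included, gave as many as the real 181, and the highest other, 1483, was several times that, which points to a structure of the samples. These splits do not decide either: in each of the other 14 part of the strain or ploidy difference itself enters the interaction. The 15 other splits without it, with a highest count of 0, are too few for a share under 0.05.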

How the results depend on the processing

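Leaving out mixture replicate 5 in all comparisons, and hybrid replicates 1 and 6, were tests chosen after the data were seen. Over the alternatives, named genes kept direction and side of the threshold in 7494 cases, lost the call in 241, gained it in 9 and reversed in 0; gene lists kept it in 2430, lost it in 203 and reversed in 1. That one, cytoplasmic ribosomal proteins in hybrid against mixture, had a value of 0.10 without hybrid replicates 1 and 6 (adjusted p = 0.976). An estimated correlation alone kept 39 list calls and lost 74. Outside the midparent comparisons, 1 probe set per gene, array weights and a variance trend left the list test unchanged. Their list cases there could not differ and say nothing about stability. For the counts below the cause was not tested. Quantile normalization gave 285 for the interaction and 441 for mixture against midparent, where leaving out the dimmest 25% gave 327, a replicate block 509 and a fit on the compared groups 1. That fit gave 2478 for strain in diploids. Array weights gave 2593 and 3744 for strain in haploids and diploids, 738 for the interaction, 1358 and 1993 for ploidy in BY and RM, 4638 for hybrid against midparent, 2230 for mixture against midparent, 4615 for hybrid against mixture and 2433 beyond ploidy. With 1 probe set per gene fewer were tested, and unnamed ones were left out. These had made up 229 of 589 calls for ploidy in BY and 454 of 791 for mixture against midparent. Counts were then 1021 for strain in haploids, 117 for the interaction, 165 and 472 for ploidy in BY and RM, and 154 for mixture against midparent. Without mixture replicate 5 they were 2244 and 2157 for strain in haploids and diploids, 296 for the interaction, 803 and 1172 for ploidy in BY and RM, and 2657 for hybrid against midparent. Without hybrid replicates 1 and 6 they were 685 for hybrid against midparent and 292 beyond ploidy. That fit had fewer arrays, and the medians of the ribosome biogenesis and stress lists were smaller too, as given above. Leaving out each array of the compared groups in turn gave 1327 to 1548 and 1164 to 1379 for strain in haploids and diploids, 121 to 203 for the interaction, 474 to 561 and 543 to 808 for ploidy in BY and RM, 1174 to 1931 for hybrid against midparent, 292 (RM haploid replicate 2) to 1066 for mixture against midparent, with 472 without BY haploid replicate 2 and 513 without mixture replicate 1, 2261 to 2784 for hybrid against mixture, and 310 (mixture replicate 3) to 777 (hybrid replicate 4) beyond ploidy. Over strain-called probe sets that differed by over 1 in log2, 31.6% and 17.5% were nearer RM in segregants 1 and 2, and 33.5% and 24.02% in the segregant hybrids. No measure of signal over background comes with the values, so weak signals could not be told from none.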

Other observations

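The segregant values are single arrays with no test chosen after they were seen. MF(ALPHA)1 was at 13.15 and 13.19 in segregants 1 and 2, and GPA1, of the pheromone pathway, at 8.45 and 8.22. In the segregant hybrids GPA1 was at 5.79 and 5.93. URA3 was at 9.18 and 9.21 in the segregants. The segregant hybrids had LYS2 at 8.44 and 8.39.

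HAP1, a regulator of respiratory genes, is measured by probe sets that differed in their calls, the one used for naming being able to share sequence with relatives. In haploids that probe set gave -0.71 (adjusted p = 0.25), whereas another gave -0.87 (adjusted p = 6.8e-05).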
